A study of Mus musculus with 28 samples.

How the data were processed

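Intracellular contents of single M1 neurons were collected at postnatal day 30 and converted to libraries with a SMARTer low-input kit and a Nextera XT kit, per the labels' protocols. The libraries were sequenced as single reads of 51 cycles on an Illumina instrument. Reads were demultiplexed with CASAVA 1.8 and filtered for quality with the FASTX-Toolkit, per the labels' protocols. The submitters' processing notes name Bowtie2, Cufflinks 2.2.1 and the genome build GRCm38, without their settings. How the Cufflinks output became the deposited values is not given in the sources used here.

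The deposited values are on a log scale and were treated as log2. The base is not stated. With base 2, the length-weighted sum of the values of a neuron is between 0.742 and 1.78 times the total that FPKM values are built around, whereas base e gives 16.4 to 44.5 times that total. The sum covers only genes of the table, so plain FPKM values would be expected to stay below the total. Sums above it mean that the values may not be plain log2 FPKM, and base 2 remains an assumption. If the base were another one, all differences would change by 1 common factor. The table is described as holding genes above a cut-off that is not stated, so the genes are a selection, and the selection may not be independent of the groups. It held 1024 genes in 28 columns, 1 per neuron, and 0 columns of other samples. All of the values were above 1. The number of reads per neuron is unknown, so no interval that needs it is given.

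Per the labels, samples were grouped by reporter state and exposure into 7 RFP-negative EtOH, 15 RFP-positive EtOH and 6 RFP-negative PBS neurons. The series' design text counts 5 PBS neurons, while 6 PBS samples and 6 columns exist, and all 6 were used. The time course label of the PBS samples mentions EtOH, whereas their titles and exposure labels give PBS. The titles and exposure labels were followed, and each comparison with PBS neurons rests on that reading. The labels do not name the animal of a neuron. Neurons of 1 animal share its litter and handling, so p-values over neurons would not measure the difference between exposures, and none are given. Each group was treated as 1 sample and described by its neurons.

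The grouping, the 3 comparisons, the gene lists, the markers, the rule for named genes and most of the alternatives tried were fixed before the data were examined. The plan had assumed linear values and used log2(value + 1). Because the deposited values are already logarithmic, differences of group means of the deposited values were used instead. The planned detection limit of a value of at least 1 removed 0 genes, since every value passed it. A limit at the trough of the histogram of all values (bins of 0.25) was chosen after the data had been seen and is used to describe how many neurons lay in the upper modes. A value below the trough is not taken as absence of the transcript.

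The rule for named genes took, per comparison, Kcnn2 and its family and the 10 genes with the largest positive and the 10 with the largest negative difference of means. It asked for a value of at least 1 in at least 50% of the neurons of the higher group, and it passed over pseudogenes, predicted genes, Y-linked genes, Xist and genes without a symbol, which here included 1 gene known only by a clone name. It also took the 3 members of each gene list and marker list with the largest absolute difference, some of which are not reported here. For each of the 18 gene lists with at least 4 measured members (12 lists), the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these neurons and is not a test. Of the 9 marker lists, those of pyramidal neurons (Nrgn), upper layers (Mef2c), interneurons (Gad1), astrocytes (Slc1a2 and Aldoc), oligodendrocytes (Mbp) and microglia (Csf1r and Cst3) had genes in the table, and those of deep layers, endothelial cells and blood had 0, as had the list of apoptosis regulators. Shares of neurons are given with exact Clopper-Pearson intervals (95%), or with a limit of 3 neurons for a share of 0.

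Gene identifiers were matched to GENCODE M21 (GRCm38), where 1020 of 1024 were found, and coordinates are 1-based. The exons of 48 of 125 named genes overlap those of another annotated gene, 38 of them on the opposite strand. The kits do not keep strand and the treatment of reads with several matches is not given, so values of such genes, and of ribosomal proteins, tubulins and other genes with near-identical copies, can include reads of another gene.

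Exactly equal values were used to look for separate treatment of neurons. Of the values, 143 occurred more than once, each within 1 gene. Neurons with fewer than 5 such values were taken as a small set, which held 4 neurons, and the other 24 as a large set. The small set held 2 equal pairs, with 1 shared value per neuron, so its neurons form separate pairs and not 1 linked group. Because a low number of shared values defined the small set, few equal pairs between the sets were possible. Their absence is therefore no test of separate treatment. Whether the authors adjusted the sets separately is not recorded.

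The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. It was tested on simulated data for RFP-positive against RFP-negative EtOH neurons, with 1024 genes of which 200 were shifted by 2. The shifted genes gave a mean difference of 2.04 and the others of 0.01. Of 50 lists of 12 shifted genes, 78% lay above the middle 95% of the random lists, and of 100 lists of other genes 4% lay outside the middle 95%. The simulated values were independent normal draws with each gene's mean and SD. They lacked the modes of the real values and any variation shared by genes within a neuron, so these rates may not hold for lists whose members vary together. Alternatives covered pseudocounts of 0.1 and 1 on values returned to the linear scale, upper quartile scaling, centring on the neuron median, within-neuron ranks, medians, arithmetic means, pairing by replicate number, each neuron left out, the large set alone, neurons with Gad1 below the trough, other detection limits and random lists not matched on expression.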

Results

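The transcriptomes of 28 single neurons from the primary motor cortex (M1) of CD1 mice were examined at postnatal day 30. The embryos had received 3 plasmids by in utero electroporation into M1 at embryonic day 15: a GFP plasmid that labels every electroporated cell, a recombinase (FLPo) under a heat shock response element, and an RFP reporter that the recombinase switches on. RFP therefore marks cells in which the heat shock response element had been active. The dams were injected intraperitoneally with ethanol (EtOH) or with phosphate-buffered saline (PBS) on embryonic days 16 and 17. The neurons fell into 3 groups: 7 RFP-negative EtOH neurons, 15 RFP-positive EtOH neurons and 6 RFP-negative PBS neurons. The ethanol dose of a given neuron's dam, 4.0 or 1.0 g/kg, was not stated.

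The deposited table held 1024 genes, each with 1 value per neuron on a log scale that was taken as log2. Total read counts per neuron were not part of it, so the sequencing depth is unknown. The 28672 values ran from 1.00 to 13.2 and had 3 modes. The lowest mode, between 1.75 and 2.0, held 3277 values, and the others lay at 5.75 to 6.0 and at 9.5 to 9.75. The trough above the lowest mode began at 4, where the bin held 222 values, and "above the trough" refers to values over 4 throughout. The number of genes above the trough per neuron had a median of 327 in RFP-negative EtOH neurons (range 274 to 366), 357 in RFP-positive EtOH neurons (273 to 434) and 323.5 in PBS neurons (286 to 412).

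No label names the animal a neuron came from, so each group was treated as 1 sample. Values are group means ± SD across neurons, and comparisons are differences of group means on the log scale without p-values. The neurons were also split into a set of 24 and a set of 4 by how many values they shared exactly with other neurons. The small set held RFP-negative EtOH neuron 1, RFP-positive EtOH neurons 1 and 2, and PBS neuron 6, which is too few for a comparison of its own. Differences within the large set, with 6, 13 and 5 neurons, are given beside the pooled ones for Kcnn2 and the gene lists. For the 20 genes named for the size of their difference in each comparison, the large set gave the same sign in all cases. The genes were picked for large differences over neurons that mostly belong to this set, so a change of sign was unlikely from the start. The median absolute shift was 0.36, 0.37 and 0.44 for RFP-positive against RFP-negative EtOH, RFP-negative EtOH against PBS and RFP-positive EtOH against PBS neurons. The largest shifts were from -3.19 to -4.21 for Nrep in the first of these, and from -4.87 to -5.81 and from -3.83 to -5.05 for Tmem178b in the others. Of the 157 differences of Kcnn2 and of list and marker members chosen for naming, 48 moved by over 1.5 times within the large set, 9 of them with a change of sign.

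Markers of cortical pyramidal neurons were high in nearly all of the neurons. Nrgn, which encodes the calmodulin-binding protein neurogranin, lay above the trough in 7 of 7 RFP-negative EtOH, 15 of 15 RFP-positive EtOH and 5 of 6 PBS neurons, with means of 7.82 ± 1.45, 8.31 ± 1.24 and 7.02 ± 2.17. Mef2c, a transcription factor of cortical neurons, lay above it in 6 of 7, 13 of 15 and 6 of 6 neurons. Gad1, which encodes the GABA-synthesising enzyme of inhibitory neurons, lay above it in 2 of 7, 3 of 15 and 1 of 6 neurons. Glial transcripts were also present. Mbp, a myelin protein of oligodendrocytes, had means of 3.25 ± 2.23, 3.60 ± 1.65 and 6.96 ± 3.68 in the same order of groups. Slc1a2, the astrocytic glutamate transporter, had means of 4.37 ± 3.33, 5.50 ± 3.26 and 6.43 ± 3.28. Cst3, a secreted protease inhibitor enriched in microglia, had means of 4.60 ± 2.57, 5.32 ± 3.48 and 4.39 ± 2.61.

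The comparison of RFP-positive with RFP-negative neurons after ethanol asks how neurons whose heat shock reporter had been activated differ from RFP-negative neurons that were also exposed to ethanol, at doses and in animals that the labels do not match between the groups. Kcnn2, which encodes a small-conductance calcium-activated potassium channel that contributes to the afterhyperpolarization following action potentials, had a mean of 3.76 ± 2.52 (SD, n = 15) in RFP-positive and 2.18 ± 0.48 (SD, n = 7) in RFP-negative EtOH neurons, a difference of 1.59. It lay above the trough in 6 of 15 RFP-positive neurons and in 0 of 7 RFP-negative EtOH neurons. The genes with the largest higher means in RFP-positive neurons were Nme7 and Tspan7, and those with the largest lower means were the vesicle traffic GTPase Rab14 and the protein modifier Sumo2. Members of the GABA receptor and unfolded protein response lists mostly had higher means in RFP-positive neurons, and members of the nuclear-encoded oxidative phosphorylation list mostly had lower ones.

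Kcnn2 (ENSMUSG00000054477) lies on the plus strand of chromosome 18 from 45268860 to 45686024 (GRCm38), and its exons overlap by up to 323 bases with transcripts annotated on the opposite strand. The library kits named in the labels do not keep strand, so reads from the 2 strands cannot be told apart. The share of RFP-positive neurons above the trough was 40.0% (95% exact interval 16.3 to 67.7%), and the 0 of 7 RFP-negative EtOH neurons allows a share of up to 42.9% by a limit of 3 neurons. These bounds cover counting error only, and they overlap. The 6 RFP-positive neurons were numbers 2, 3, 8, 13, 14 and 15, with values of 7.46, 4.18, 9.77, 4.89, 6.22 and 5.45. The remaining 9 lay between 1.36 and 3.12, within the lowest mode like the RFP-negative neurons. The difference of 1.59 was smaller than the SD among RFP-positive neurons. It was 1.40 within the large set, where 5 of 13 RFP-positive neurons lay above the trough. It was 0.78 among neurons with Gad1 below the trough, where 4 of 12 did. The median difference over all 1024 genes was 0.31, so Kcnn2 stood 1.27 above it. Kcnn1, Kcnn3 and Kcnn4, the other genes of the family, were not among the genes of the table.

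**Figure D1:**
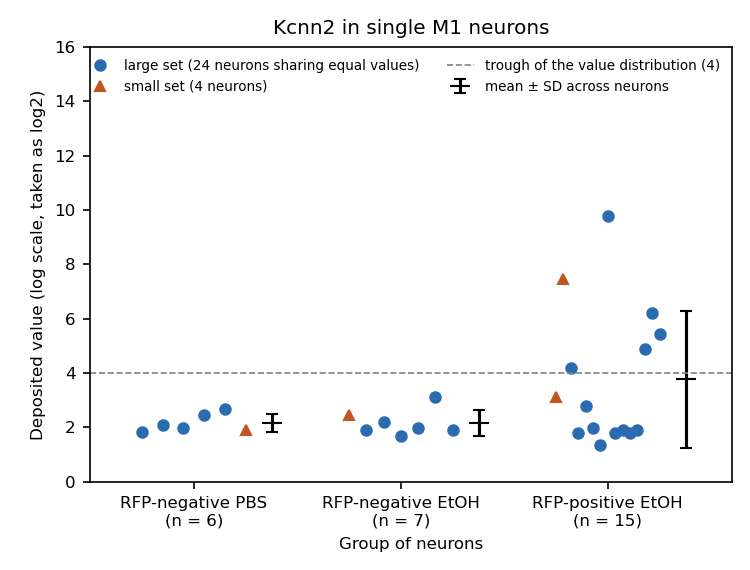
Kcnn2 in each neuron, with the group on the x axis and the deposited value (log scale, taken as log2) on the y axis. Circles are neurons of the large set, triangles those of the small set, bars the mean ± SD across neurons, and the dashed line the trough at 4. The 6 neurons above the line are all RFP-positive, and 9 RFP-positive neurons lie below it with the 13 RFP-negative ones.

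Of the 10 genes with the largest higher means in RFP-positive EtOH neurons, Nme7 (ENSMUSG00000026575, chromosome 1, 164304121 to 164437725), a nucleoside diphosphate kinase family member, averaged 7.38 ± 2.76 against 3.66 ± 2.26, a difference of 3.71. Exons of Nme7 overlap those of Atp1b1 and Blzf1 on the opposite strand by up to 383 and 189 bases, so its values can include reads of these genes. Tspan7, a tetraspanin of the cell membrane, averaged 7.91 ± 2.29 against 4.22 ± 1.80 and lay above the trough in 14 of 15 against 4 of 7 neurons. Hacd3, an enzyme of very-long-chain fatty acid elongation, Scrn1 and Ogt, which attaches O-GlcNAc to proteins, lay above the trough in 9, 10 and 8 RFP-positive neurons and in 0 RFP-negative EtOH neurons, with differences of 3.42, 3.30 and 3.09. Ncl, the nucleolar protein nucleolin, lay above it in 12 of 15 against 1 of 7 neurons and differed by 3.30. Atp6v0c, a subunit of the proton pump that acidifies vesicles, differed by 3.37. Mrfap1, Tmx2 and Itm2c differed by 3.18, 3.16 and 3.14. For Mrfap1 and Tmx2 the differences within the large set were 2.31 and 2.39.

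Of the 10 genes with the largest lower means, Rab14 (ENSMUSG00000026878, chromosome 2, 35180205 to 35201120), a GTPase of endosome and Golgi traffic, averaged 3.63 ± 3.50 in RFP-positive and 8.33 ± 3.37 in RFP-negative EtOH neurons, a difference of -4.70. It lay above the trough in 4 of 15 against 6 of 7 neurons. Sumo2, a small ubiquitin-like modifier, differed by -3.85 with 3 of 15 against 6 of 7 neurons above the trough. Napa, which acts in the disassembly of SNARE complexes, differed by -3.66. Fgf13, an intracellular protein that binds voltage-gated sodium channels, averaged 2.11 ± 0.79 with 0 of 15 RFP-positive neurons above the trough, against 5.52 ± 4.39 with 4 of 7. Nrep differed by -3.19, and Prepl and Prkar2a, a regulatory subunit of protein kinase A, by -3.14 each. Pea15a and Sbds, a ribosome maturation factor, differed by -2.97 each. Cox4i1, a subunit of cytochrome c oxidase, averaged 4.76 ± 3.40 against 7.71 ± 1.49 and lay above the trough in 6 of 15 against 7 of 7 neurons.

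The list medians were compared with those of 10000 random lists of the same size and expression. All 4 measured members of the list named for voltage-gated sodium and calcium channels (Scn3a, Scn3b, Cacna1e and Cacng3) had higher means in RFP-positive neurons. The list's median was 0.77 at percentile 75.6. It was 1.22 within the large set, 0.37 without RFP-positive EtOH neuron 5 and 0.18 among neurons with Gad1 below the trough. Of the 4 GABA receptor genes, 3 had higher means, with a median of 1.44 at percentile 94.8, and of 1.30 within the large set. Among them Gabbr1, a subunit of the GABA-B receptor, differed by 1.73. Of the 6 unfolded protein response genes, 5 had higher means, with a median of 1.39 at the upper edge of the middle 95% of random lists, and of 1.37 within the large set. The endoplasmic reticulum chaperones Canx and Hsp90b1 differed by 2.37 and 2.24, and the disulfide isomerase Pdia3 by 1.60. Both lists kept a positive median under every alternative setting that was run. Of the 20 nuclear-encoded oxidative phosphorylation genes, 15 had lower means, with a median of -0.69 at percentile 3.30, and of -0.70 within the large set. The electron carrier Cycs differed by -2.61 and Cox7b by -2.64. This list's median was 0.01 when arithmetic means were compared and -0.36 without RFP-negative EtOH neuron 1.

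The 12 measured heat shock chaperones had a median difference of -0.22 at percentile 18.4, with 5 higher and 7 lower means, and it was -0.01 within the large set and 0.23 without RFP-negative EtOH neuron 5. Cct3, a subunit of the cytosolic chaperonin, Hspa12a and the small heat shock protein Cryab differed by 1.76, 1.41 and 1.38. The 19 axon and cytoskeleton genes had a median of 0.70 at percentile 97.1, and 0.35 both within the large set and without RFP-negative EtOH neuron 5. Nefl, the neurofilament light chain, averaged 7.00 ± 2.95 against 4.21 ± 2.65, and Actb and Tuba1b, which encode actin and tubulin, differed by 2.09 and 2.04. Exons of Nefl overlap those of Nefm on the opposite strand by up to 1108 bases, so its values can include reads of Nefm. The medians of the ribosomal protein, synaptic vesicle, postsynaptic scaffold, antioxidant, histone and DNA modifying and mitochondrially encoded lists were 0.38, 0.32, -0.76, -0.13, -0.05 and 0.37, and within the large set 0.39, -0.27, -0.57, -0.07, 0.09 and 0.01. All 6 pooled medians lay within the middle 95% of their random lists. Snap25 of the vesicle fusion machinery averaged 9.79 ± 1.57 against 11.28 ± 0.46, while 6 of the 8 genes of the synaptic vesicle list had higher means in RFP-positive neurons. The immediate early gene Fos lay above the trough in 6 of 15 against 1 of 7 neurons, with a difference of 1.95, and Junb differed by 1.15.

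Members of the lists with fewer than 4 measured genes were Kcnc2 and Kcnv1 of the other potassium channels, Grm3 of the glutamate receptors and Akr1a1 of ethanol and aldehyde metabolism, which differed by 0.84, 0.20, 0.37 and 0.33. Within the large set Kcnv1, Grm3 and Akr1a1 differed by 1.18, 0.57 and -0.71. Marker genes of other cell types differed between the groups to a similar extent. Slc1a2 differed by 1.13, Aldoc, an astrocyte-enriched aldolase, by 1.06 and the microglial receptor Csf1r by -0.85. Means were higher in RFP-positive neurons for 614 genes and lower for 410. Scaling each neuron to the same upper quartile moved the difference of every gene by -0.51, which put the median of all genes at -0.20, so that differences are best read relative to that median. No gene named from the largest differences changed direction under any setting that was run, which their selection for size in these same neurons made likely from the start.

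**Figure D2:**
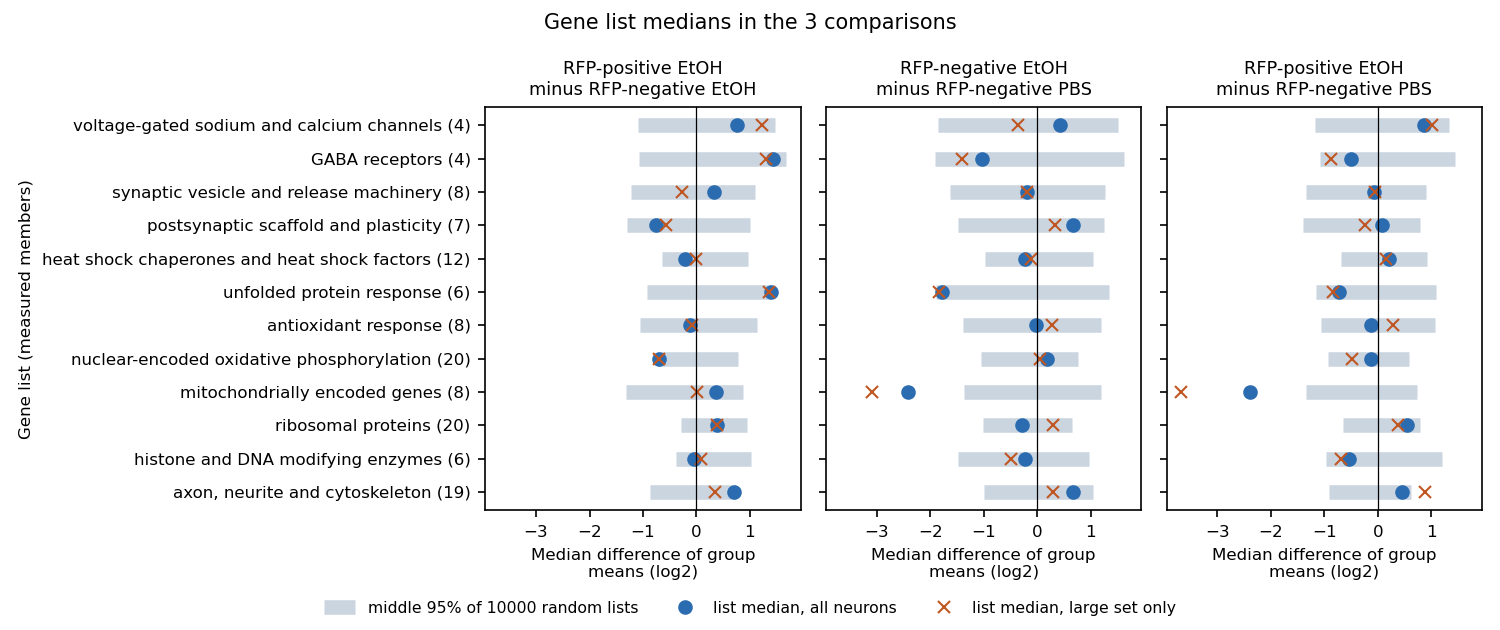
Median difference of group means (log2, x axis) for the 12 gene lists with at least 4 measured members (y axis, members in brackets) in each of the 3 comparisons. Circles are medians over all neurons, crosses medians within the large set, and grey bars the middle 95% of 10000 random lists for all neurons. Over all neurons, the mitochondrially encoded genes lie outside the bars, at -2.41 and -2.38, in both comparisons with PBS neurons.

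The comparison of RFP-negative EtOH with RFP-negative PBS neurons asks how ethanol-exposed neurons without reporter activation differ from neurons of the injection control. All 8 measured mitochondrially encoded genes had lower means in the EtOH neurons, with a median difference of -2.41. The gene with the largest lower mean was Hnrnpk, an RNA-binding protein, at 4.08 ± 2.52 (SD, n = 7) against 10.27 ± 0.69 (SD, n = 6). Cacybp and Rab14 led the higher means, with differences of 4.61 and 4.13. Kcnn2 averaged 2.18 ± 0.48 against 2.16 ± 0.34 and lay above the trough in 0 of 7 and 0 of 6 neurons, the latter allowing a share of up to 50%. The Kcnn2 difference of 0.02, and of -0.08 within the large set, was smaller than either SD.

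The mitochondrially encoded genes specify subunits of the respiratory chain and of ATP synthase. The median of the 8 genes per neuron averaged 6.77 ± 3.01 in RFP-negative EtOH neurons, with a range of 2.87 to 10.8, and 9.49 ± 0.88 in PBS neurons, with a range of 7.85 to 10.1. The list's median difference lay at percentile 0.12 of the random lists and was -3.10 within the large set. The differences were largest for mt-Nd1 (-3.70), mt-Nd6 (-3.65) and mt-Nd2 (-2.97), which encode complex I subunits and lay above the trough in 4, 2 and 4 of 7 EtOH neurons and in 6 of 6 PBS neurons each. mt-Nd6 is encoded on the strand opposite to the other members. The median was -0.94 when arithmetic means were compared in place of means of log values. Of the 20 nuclear-encoded oxidative phosphorylation genes, 13 had higher means in the EtOH neurons, with a median of 0.18 at percentile 73.5, and of 0.05 within the large set. Cox4i1 differed by 3.64, while Ndufv1 of complex I and Atp5a1 of ATP synthase differed by -3.82 and -3.24.

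**Figure D3:**
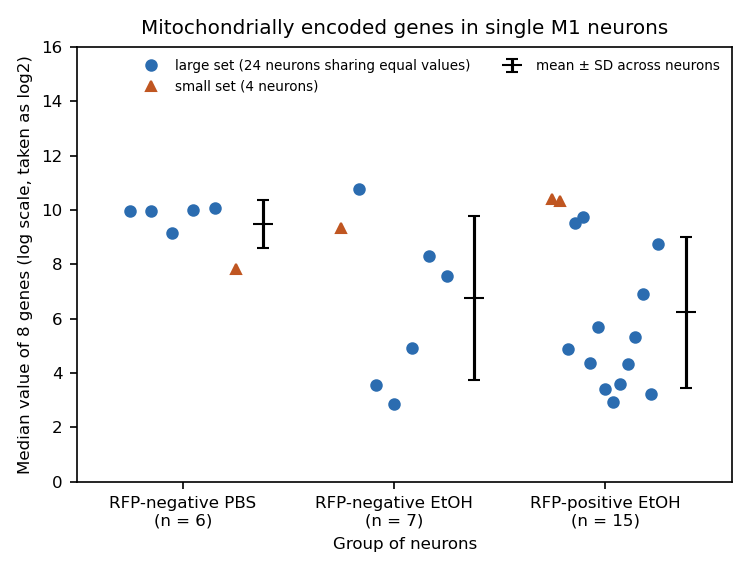
Median value of the 8 measured mitochondrially encoded genes in each neuron, with the group on the x axis and the value (log scale, taken as log2) on the y axis. Circles are neurons of the large set, triangles those of the small set and bars the mean ± SD across neurons. PBS neurons lie between 7.85 and 10.1, RFP-negative EtOH neurons between 2.87 and 10.8, and RFP-positive EtOH neurons between 2.95 and 10.4.

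Among the 10 genes with the largest lower means in RFP-negative EtOH neurons, Hnrnpk (ENSMUSG00000021546, chromosome 13, 58391142 to 58403343) differed by -6.18 and lay above the trough in 1 of 7 against 6 of 6 neurons. Psmb6, a catalytic subunit of the proteasome, the lysosomal protease Ctsb and the translation initiation factor Eif2s1 each lay above it in 1 of 7 against 5 of 6 neurons. Psmb6 and Eif2s1 differed by -5.04 and -4.96, and Ctsb averaged 3.31 ± 1.83 against 8.31 ± 3.41. Tmem178b and Ncbp2, a subunit of the nuclear cap-binding complex, lay above it in 0 of 7 against 4 of 6 neurons, with differences of -4.87 and -4.74. Mgea5, which removes O-GlcNAc from proteins, averaged 2.68 ± 1.20 against 7.39 ± 3.64. Sez6l2, the membrane glycoprotein Gpm6b and Psap, the precursor of lysosomal lipid-degradation cofactors, differed by -4.08, -4.04 and -4.02.

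Among the 10 genes with the largest higher means, Cacybp (ENSMUSG00000014226, chromosome 1, 160202367 to 160212875), the calcyclin-binding protein, averaged 7.27 ± 2.96 against 2.66 ± 1.96 and lay above the trough in 6 of 7 against 1 of 6 neurons. Rab14 lay above it in 6 of 7 against 3 of 6 neurons. Chmp2a, a component of the membrane-remodelling ESCRT machinery, and Rnf4, a ubiquitin ligase that acts on SUMO-modified proteins, lay above it in 6 and 5 of 7 against 0 of 6 neurons, with differences of 4.02 and 3.68. Slc25a4, the ADP/ATP carrier of the inner mitochondrial membrane, averaged 9.54 ± 1.52 against 5.81 ± 3.71. Prkar2a, Cdr1, the phosphomannomutase Pmm1 and the helicase Dhx36 differed by 3.67, 3.58, 3.44 and 3.43. The annotated exon of Cdr1 overlaps a transcript on the opposite strand over 1554 bases, so reads from both are counted without distinction.

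Of the 6 unfolded protein response genes, 5 had lower means in RFP-negative EtOH neurons, with a median of -1.78 at percentile 3.34, of -1.83 within the large set and of -1.14 without PBS neuron 1. Hsp90b1, Pdia4 and Hspa5, the chaperone BiP, differed by -3.79, -2.25 and -1.94, with Pdia4 at -1.44 within the large set. Of the 4 GABA receptor genes, 3 had lower means, with a median of -1.02 at percentile 15.4, of -1.40 within the large set and of -0.27 without PBS neuron 1. The heat shock chaperones had 6 higher and 6 lower means and a median of -0.22 at percentile 31.0, and of -0.12 within the large set. Cct6a differed by -2.19, Cryab by -1.46 and Hsp90ab1, a cytosolic chaperone that was above the trough in all 13 neurons, by 1.32. Within the large set Cryab differed by -0.39 and Hsp90ab1 by 0.81. The ribosomal proteins had a median of -0.28, and of 0.30 within the large set, with Rps19 at 3.08, Rpl14 at -2.14 (-1.37 within the large set) and Rpl37a at -1.99.

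The medians of the voltage-gated channel, synaptic vesicle, postsynaptic scaffold, antioxidant, histone and DNA modifying and axon and cytoskeleton lists were 0.44, -0.18, 0.66, -0.02, -0.22 and 0.68, all within the middle 95% of random lists. Within the large set they were -0.36, -0.19, 0.34, 0.28, -0.48 and 0.30. The last was 0.00 without PBS neuron 5. Within these lists Dync1h1, the heavy chain of dynein, differed by -3.46, Tubb4a by -2.95, Dnmt3a, a DNA methyltransferase, by -2.60, Vamp2 of the synaptic vesicle by -2.19 and Camk2b, a kinase of synaptic plasticity, by 2.03 (3.48 within the large set). Fos differed by -1.97, Kcnc2 by -2.03 and Grm3 by -1.33. Of the glial markers, whose differences did not all have the same sign, Mbp differed by -3.71, Aldoc by -2.13 and Slc1a2 by -2.06. Gad1 differed by -1.06 and reached 13.2 in PBS neuron 4. The median over all genes was -0.06, and 0.49 after upper quartile scaling, which moved every gene by 0.55. Kcnn2 stood 0.08 above that median with either scaling.

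The comparison of RFP-positive EtOH with RFP-negative PBS neurons combines ethanol exposure and reporter activation, and its difference is the sum of the other 2 comparisons for each gene. It is therefore not independent of them. Kcnn2 averaged 3.76 ± 2.52 (SD, n = 15) against 2.16 ± 0.34 (SD, n = 6), a difference of 1.61, and of 1.32 within the large set. Kcnn2 stood 1.35 above the median difference over all genes of 0.26, which upper quartile scaling moved by 0.04. All 8 mitochondrially encoded genes had lower means in RFP-positive EtOH neurons, with a median of -2.38, below each of the 10000 random lists. Hnrnpk, Eif2s1 and Psmb6 had the largest lower means, while the genes with the largest higher means included the cytoskeletal genes Tubb3, Cfl1, Wasf1 and Nefl.

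The per-neuron median of the mitochondrially encoded genes averaged 6.23 ± 2.79 in RFP-positive EtOH neurons, against 9.49 ± 0.88 in PBS neurons. Within the large set the list's median difference was -3.68, and it was -0.90 when arithmetic means were compared. mt-Nd4, mt-Nd6 and mt-Nd1 differed by -3.37, -3.25 and -3.18. Of the 20 nuclear-encoded oxidative phosphorylation genes, 10 had higher and 10 lower means, with a median of -0.12 at percentile 55.3, and of -0.49 within the large set. Atp5a1 and Ndufv1 differed by -3.31 and -2.91, and Ndufs1 by 2.19.

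Hnrnpk averaged 5.13 ± 2.68 in RFP-positive EtOH against 10.27 ± 0.69 in PBS neurons and lay above the trough in 8 of 15 against 6 of 6. Eif2s1 lay above it in 2 of 15 against 5 of 6 neurons, with a difference of -5.01, and Psmb6 in 5 of 15 against 5 of 6, with a difference of -4.31. Tmem178b, Magee1 and Ncbp2 differed by -3.83, -3.82 and -3.71. Prkar1a, a regulatory subunit of protein kinase A, averaged 5.42 ± 3.46 against 9.21 ± 1.37. Slc24a2, a sodium, calcium and potassium exchanger, differed by -3.46, and Mbp by -3.36.

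Tmx2 (ENSMUSG00000050043, chromosome 2, 84671316 to 84679140), a thioredoxin-related membrane protein, averaged 7.06 ± 3.40 in RFP-positive EtOH against 2.45 ± 1.27 in PBS neurons, a difference of 4.61. Tubb3, the neuronal beta-tubulin, differed by 3.73 with 11 of 15 against 2 of 6 neurons above the trough. Hmgcs1, an enzyme of cholesterol synthesis, lay above it in 8 of 15 against 0 of 6 neurons and differed by 3.56. Prkacb, a catalytic subunit of protein kinase A, differed by 3.39. The actin regulators Cfl1 and Wasf1 lay above the trough in 14 and 13 of 15 against 5 and 3 of 6 neurons, with differences of 2.96 and 2.92. Rps19, Nefl, Gabarap, which acts in autophagy and GABA-A receptor trafficking, and Ankrd46 differed by 2.93, 2.91, 2.89 and 2.83.

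Of the 19 axon and cytoskeleton genes, 13 had higher means, with a median of 0.45 at percentile 91.3, and of 0.22 without RFP-positive EtOH neuron 11 and 1.10 without PBS neuron 6. Within the large set it was 0.88, at percentile 99.6. The ribosomal proteins had 14 higher and 6 lower means and a median of 0.55 at percentile 87.5, of 0.38 within the large set and of 0.19 without PBS neuron 2, with Rps27a at 1.55 and Rpl4 at 1.50. The heat shock chaperones had a median of 0.21 at percentile 52.9, and of 0.16 within the large set, with Cct6a at -1.20, Chordc1 at -1.10 and Hspa8 at -0.92. The unfolded protein response and GABA receptor lists had medians of -0.73 and -0.51, and of -0.83 and -0.87 within the large set. The first was 0.41 when arithmetic means were compared, -0.12 without PBS neuron 4 and -1.34 without PBS neuron 3, and the second was 0.51 without PBS neuron 1 and -0.83 without PBS neuron 6. Pdia4 differed by -2.30, Hsp90b1 by -1.55 (-1.02 within the large set) and Gabbr1 by 2.21. The voltage-gated channel, synaptic vesicle, postsynaptic scaffold, antioxidant and histone and DNA modifying lists had medians of 0.86, -0.07, 0.08, -0.13 and -0.53, and within the large set of 1.01, -0.05, -0.24, 0.29 and -0.69. The first was 0.45 without RFP-positive EtOH neuron 5 and 1.66 without PBS neuron 1, and the last was 0.03 without PBS neuron 1 and -0.91 without PBS neuron 2. Scn3b, a sodium channel subunit, differed by 2.11, Dnmt3a by -1.67, Creb1, a transcription factor, by -1.51 and the peroxiredoxin Prdx6 by 1.24. Of the 36 list medians over the 3 comparisons, 2 lay outside the middle 95% of the random lists matched on expression, both of the mitochondrially encoded genes. Lists of random genes would give 1.8 on average, and members of 1 list can vary together more than random genes do. Against random lists not matched on expression, 5 lay outside. The further 3 were the unfolded protein response list in the comparison of RFP-positive with RFP-negative EtOH neurons (percentile 98.7) and of RFP-negative EtOH with PBS neurons (1.15), and the nuclear-encoded oxidative phosphorylation list in the first of these (0.17).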

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

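The tests of Kcnn2 within the large set and among neurons with Gad1 below the trough, the test on nuclear-encoded oxidative phosphorylation genes and the test on equal values were chosen after their results had been seen. Kcnn2 was higher on average in RFP-positive than in RFP-negative EtOH neurons, with 6 of 15 against 0 of 7 neurons above the trough. Separate treatment of the small set of neurons is not the whole cause, since the difference was 1.40 within the large set, where 5 of 13 RFP-positive neurons stayed above the trough. Interneuron content is not the whole cause either, with a difference of 0.78 and 4 of 12 RFP-positive neurons above the trough where Gad1 was below it, but the drop from 1.59 leaves a partial contribution open. The higher number of genes above the trough in RFP-positive neurons stays open, because the Kcnn2 difference lay at percentile 90.7 of the 313 other genes with 5 to 7 neurons above the trough, within their middle 95% (-1.98 to 1.93). A link of Kcnn2 with the activated reporter, the biological difference in the design, remains untested with animals unnamed.

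Mitochondrially encoded genes were higher in PBS than in RFP-negative EtOH neurons, with a list median of -2.41. Separate treatment of the small set does not account for this, since the median was -3.10 within the large set. A single neuron does not either, since the median nearest 0 with 1 neuron left out was -1.79, without PBS neuron 2. A general gain of oxidative phosphorylation transcripts in PBS neurons was not seen in the nuclear-encoded list, which leaned the other way. Of its 20 genes, 13 had higher means in RFP-negative EtOH neurons. The list's median was 0.18 and stayed between 0.07 and 0.63 with each neuron left out. Its per-neuron medians averaged 5.94 ± 0.80 in RFP-negative EtOH and 4.96 ± 1.59 in PBS neurons. That spread across neurons is wide beside the list's median, so a general gain is not excluded. Ethanol exposure stays open as an untested biological explanation, and so do differences between animals, which the labels do not name, and a part played by other cells, since Mbp, Aldoc and Slc1a2 differed by -3.71, -2.13 and -2.06 alongside.

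Equal values occurred only within a gene and only within 2 sets of neurons, with 143 equal pairs in the large and 2 in the small set. The 4 neurons of the small set shared 1 value each, against 7 to 17 in the large set. A per-gene adjustment of 2 sets of neurons treated separately would leave 0 equal pairs between the sets, and 0 were found. The small set was defined as the neurons with fewer than 5 shared values, so few such pairs were possible and this count tests nothing. Whether the sets were processed apart therefore stays open. No biological explanation was tested, and the adjustment itself is not recorded.

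A single neuron stood apart from its group in 21 of 100 groups of values tested, where chance would give about 1 in 20. The values have several modes and the named genes were picked for large differences, so that 1 neuron in another mode is enough for a gap of this kind. In RFP-negative EtOH neurons, the highest value stood apart for Hnrnpk at 9.79 in neuron 5, with the others at 2.87 to 3.35. It also did for Gpm6b at 11.2 and Eif2s1 at 6.41 in neuron 6, for Ctsb at 7.37 in neuron 7, and for Psmb6 at 8.10 and Mgea5 at 5.28 in neuron 3. Neuron 4 stood apart for Ncl at 5.83 and Ogt at 3.39, neuron 5 for Tmx2 at 9.59 and neuron 1 for Tmem178b at 2.36. The lowest value stood apart for Rab14 at 1.49 in neuron 5, with the others at 6.81 to 10.7, and in neuron 2 for Sumo2 at 2.91 and Sez6l2 at 1.28. For Ogt, Tmem178b and Sez6l2 all values of the group lay below the trough, so these gaps are within the lowest mode. Among list medians of RFP-negative EtOH neurons, that of the heat shock chaperones was 6.58 in neuron 5 against 2.30 to 3.60 in the others. The unfolded protein response median was 3.96 in neuron 4 against 2.18 to 2.83, and the nuclear-encoded oxidative phosphorylation median was 4.32 in neuron 2 against 5.76 to 6.73. In PBS neurons, neuron 1 stood apart with a GABA receptor median of 8.95 against 1.74 to 3.66 and with Nefl at 9.55. Neuron 5 stood apart with Cdr1 at 6.78 and, as the lowest, Slc24a2 at 3.04, and neuron 4 with Rps19 at 5.03.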

How the results depend on the processing

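The large set, neurons with Gad1 below the trough, centring, ranks, the pseudocount of 1 and the limits of 3.5 and 5 were chosen after seeing the data, and the other settings before. None of the 60 differences of genes named for their size changed direction under any setting. They were picked for that size in these same neurons, so a kept direction was likely from the start and says little about other genes. The median difference of all genes between RFP-positive and RFP-negative EtOH neurons, 0.31, was -0.20 with upper quartile scaling and 1.03 with arithmetic means. That between RFP-negative EtOH and PBS neurons, -0.06, was 0.49 with upper quartile scaling, and the Kcnn2 difference there was 0.57 in place of 0.02, and -0.05 with medians and -0.08 within the large set. That between RFP-positive EtOH and PBS neurons, 0.26, was 0.74 with arithmetic means. The Kcnn2 difference between RFP-positive and RFP-negative EtOH neurons, 1.59, was 0.82 with medians and 3.88 with arithmetic means, and that between RFP-positive EtOH and PBS neurons, 1.61, was 0.76 and 3.93. The cause was not tested, except that upper quartile scaling adds 1 constant per neuron and so shifts all genes alike. Leaving out each neuron in turn gave Kcnn2 differences of 1.16 (without RFP-positive EtOH neuron 8) to 1.76, of -0.14 to 0.12 and of 1.18 to 1.78 in the 3 comparisons. Ranked within each neuron, Kcnn2 stood on average at percentile 31.0, 48.1 and 35.9 of the genes in RFP-negative EtOH, RFP-positive EtOH and PBS neurons. Its share above the limit in RFP-positive neurons was 40.0% at 3.5 and 26.7% at 5, and 0 in the other groups at both. Of the 36 list medians, 8 changed direction with upper quartile scaling, 11 with arithmetic means, 6 with medians, 7 within the large set and 18 on leaving out at least 1 neuron. On leaving out 1 neuron, 31 of the 36 moved by over 1.5 times or changed direction. The other 5 were those of the mitochondrially encoded genes in both comparisons with PBS neurons, and of the GABA receptors, the unfolded protein response and the postsynaptic scaffold between RFP-positive and RFP-negative EtOH neurons. The medians of the mitochondrially encoded genes against PBS neurons kept their direction throughout.

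Under the planned limit of at least 1, all 1024 genes passed in every neuron, and at a value of at least 5 the medians per neuron were 293 in RFP-negative EtOH, 321 in RFP-positive EtOH and 287.5 in PBS neurons. With the replicate block, in which neurons of the same number are paired, the Kcnn2 differences were 1.07, 0.06 and 1.40. The numbers share only a name: correlations of same-numbered neurons' deviations ran from -0.16 to 0.15, and the best match had the same number in 4 of 38 cases. A setting without a filter moved nothing, because the filter removed 0 genes. The alternatives for p-values of the table were not run, because the analysed table holds expression values. Depth is unknown and limits what a value below the trough can say.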

Other observations

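All of the results in this part were looked for after the data had been seen. Lysosomal genes showed a pattern that no list fixed in advance covered. Ctsb, Ctsd, Psap and Lamp1 all had lower means in RFP-negative EtOH than in PBS neurons, with a median difference of -3.29 at percentile 0.03 of random lists, and of -3.21 within the large set. Ctsb averaged 3.31 ± 1.83 in RFP-negative EtOH, 6.20 ± 3.87 in RFP-positive EtOH and 8.31 ± 3.41 in PBS neurons. Psap averaged 2.46 ± 0.73, 4.69 ± 3.01 and 6.47 ± 4.19, and Ctsd, another lysosomal protease, 3.13 ± 1.77, 3.91 ± 2.99 and 5.70 ± 4.19. All 4 had higher means in RFP-positive than in RFP-negative EtOH neurons, with a median of 1.50. These directions held with upper quartile scaling, at -2.74 and 0.99. Ctsb and Psap were already among the genes with the largest differences, so the family is not independent of them. Some of the glial markers also had higher means in PBS than in RFP-negative EtOH neurons, with Mbp at 6.96 against 3.25, Aldoc at 3.98 against 1.85 and Slc1a2 at 6.43 against 4.37. Which cells the lysosomal transcripts came from was not tested.

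The Ywha genes, which encode phosphoprotein-binding adaptors abundant in neurons, went the other way. Of the 6 genes, 5 had higher means in RFP-negative EtOH than in PBS neurons (median 1.56, percentile 98.5) and all 6 had lower means in RFP-positive than in RFP-negative EtOH neurons (median -1.38, percentile 2.33). With upper quartile scaling the medians were 2.12 and -1.89, and within the large set 0.86 and -1.68. Ywhah averaged 10.42 ± 0.49 in RFP-negative EtOH, 7.63 ± 3.76 in RFP-positive EtOH and 8.74 ± 2.08 in PBS neurons. The ubiquitin-conjugating enzymes had a median of 1.44 between RFP-negative EtOH and PBS neurons (percentile 98.9, and 1.99 with upper quartile scaling), and the Rab GTPases, which include Rab14, one of -1.15 between RFP-positive and RFP-negative EtOH neurons (percentile 2.28, and -1.66 with upper quartile scaling). In all, 13 families were formed from gene symbols, and 8 of their 39 medians lay outside the middle 95% of random lists, where lists of random genes would give 1.95 on average. The families were chosen after the data had been seen, share the same groups and can have members that vary together, so this count is not a test.

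The enzymes that add and remove O-GlcNAc stood among the named genes of different comparisons. Ogt, which adds it, averaged 2.33 ± 0.49 in RFP-negative EtOH, 5.42 ± 3.53 in RFP-positive EtOH and 4.28 ± 3.50 in PBS neurons. Mgea5, which removes it, averaged 2.68 ± 1.20, 5.41 ± 3.84 and 7.39 ± 3.64. They lay above the trough in 0 and 1 of 7 RFP-negative EtOH, 8 and 7 of 15 RFP-positive EtOH and 2 and 5 of 6 PBS neurons.

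Kcnn2 was 1 of 7 genes that lay above the trough in at least 6 RFP-positive neurons and in 0 RFP-negative neurons of either exposure. The others were Fyn, a tyrosine kinase, in 8 RFP-positive neurons, Ankrd46, Dusp14 and Myh10, a non-muscle myosin heavy chain, in 7 each, and Zfp281 and Ifrd1 in 6 each. Fyn averaged 4.34 in RFP-positive EtOH, 2.16 in RFP-negative EtOH and 1.84 in PBS neurons. Among the 313 other genes with 5 to 7 neurons above the trough together with Kcnn2 itself, 17 had 0 RFP-negative neurons above it.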
